A study of Mus musculus with 2 samples.

How the data were processed

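Total RNA of UVB-induced skin tumours from male wild-type and P2ry6-/- mice was profiled on single-colour Agilent arrays, 1 array per genotype and 2 in all. Per the labels' protocols, Cy3-labelled cRNA was made from 0.2 µg of RNA with a linear amplification kit. How many tumours or mice went into each RNA sample is not given in the sources used here. Each array file is the scanner software's output. Per the submitters' processing notes and per the file headers the authors extracted each spot's intensity with Agilent Feature Extraction 10.7.1.1, which subtracted a spatially fitted background, detrended the signal across the array and replaced values near background by surrogates. No normalization between arrays had been applied to these intensities. The file headers place both arrays on 1 slide in 1 scan, so slide and scan do not separate the genotypes. The authors also deposited a table of log2 values for the same arrays. Set against the scanner files, its columns correlated with the log2 processed signal at r = 0.9999 (wild-type-labelled) and 0.9997 (knockout-labelled) over 56594 probes, and the sorted values of both columns differed by at most 0.00104, with a median of 4.96 in each. They are therefore the log2 processed signal after quantile normalization, as read from the values, and the method that made them is not given in the sources used here.

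Each array held 62976 spots, of which 59305 were non-control spots of 56605 probes. No spot was saturated. Spots marked by the scanner software as non-uniform or as population outliers were left out (102 on the wild-type-labelled and 105 on the knockout-labelled array), which removed 11 probes. The value of a probe was the log2 processed signal minus the array's 75th percentile of it over non-control probes, with the spots of a probe averaged. A probe was measured where most of its spots were well above background, by the scanner software's own mark, on both arrays. The value of a gene was the mean over its measured probes, and a gene was called at least 2-fold apart where the difference, knockout-labelled minus wild-type-labelled, was at least 1 log2 unit in size. Of 6731 genes with 2 or more measured probes, 2448 had probes on different sides of 0, among them 6 of the genes called 2-fold apart. A gene above background on one array only was given a bound: its level on the bright array against the higher of the dim array's lowest signal well above background and the dim probe's own. Neither array gave a level for 15325 genes, and 22 were above background on both through different probes. Those were not compared.

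Probes were named through RefSeq accessions in a gene table of the assembly GRCm38.p6, used for names alone: 31453 probes kept the symbol in the array file, 1535 had it updated, and 23606 kept the array file's own name because no accession matched. This gave 37321 gene names, of which 19873 were measured on both arrays. Probe positions are those of the array files, on mm9 per the file headers. No exon or untranslated region annotation of that build was used here.

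With 1 array per group there are no residual degrees of freedom, so no test between genotypes was run. Gene groups were described by their median, their counts past 2-fold, and the percentile of their median among 10000 random lists of the same size, matched on mean level in 20 bins. The 40 lists covered keratinocyte states (basal, suprabasal and cornified, hyperproliferative and stress, simple epithelial and tumour progression keratins), appendages (hair follicle and hair shaft, sebaceous gland), stroma (fibroblast, matrix remodelling and activated stroma, epithelial-mesenchymal transition, smooth muscle and pericyte, endothelial), immune cells (macrophage and monocyte, neutrophil, T and NK, B and plasma, dendritic and Langerhans, mast), other cells (skeletal muscle, adipocyte, melanocyte, Schwann and neural, red blood cell), signalling (purinergic, YAP/TAZ targets, Hippo components, Wnt/beta-catenin targets, Wnt ligands and receptors, MAPK output, immediate early, cytokines and chemokines, interferon response), and cell state (cell cycle, p53 targets, nucleotide excision repair, hypoxia and glycolysis, unfolded protein response, NRF2 targets, ribosomal proteins, reference genes, sex-linked genes). The lists, the rule for named genes, the 2-fold threshold and the alternatives were chosen before the data were examined, except for the spike-in scale and the gene families, which were added later. The rule named P2ry6, the 15 genes with the greatest positive and the 15 with the greatest negative difference among those with an established symbol and probes that agree in sign, the 5 with the greatest bound in each direction, up to 4 members of each list by size of difference, and the sex-linked genes. Some genes that the rule takes are not reported here.

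The alternatives were normexp background correction with an offset of 50 on mean and local background signals, quantile and loess normalization between the arrays, centring on the median of probes above background, the authors' deposited log2 values, no filter and a stricter filter on dim probes, the probe with the highest signal per gene, a 3-fold threshold, and keeping the spots marked as outliers. The stricter filter kept probes that lay, on both arrays, above the array's median signal of probes well above background. A gene that was low on either array could therefore drop out. Loess used a span of 0.7 with 3 iterations. The spike-in scale took the mean difference of 8 spike-in probes off every gene.

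The calculation was tested on simulated data with 20984 genes, 200 of them changed, and a noise SD of 0.2 log2 units per array. It recovered past 2-fold 96% of genes changed by 1.5 log2 units, 98% of those changed by −1.5 and 100% of those changed by 3, with 7 unchanged genes past 2-fold. The simulated noise was independent between probes, every probe was set above background, and variation between tumours or animals was left out. The 7 genes are therefore no estimate of false calls on the real arrays. Of 200 lists drawn at random from all the simulated genes, changed ones included, 5% lay outside the central 95% range. Random draws give about that share by construction, so it says nothing of lists whose genes vary together. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and limma 3.58.1 in R 4.3.3. The number of arrays limits the precision of every value.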

Results

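Gene expression was measured in skin tumours that chronic ultraviolet B (UVB) irradiation had induced on the backs of male mice, 1 tumour RNA sample from wild-type mice and 1 from P2ry6-/- mice. P2ry6 encodes a G protein-coupled receptor activated by the nucleotide UDP. Mice were 2 months old at the start. The UVB dose was 180 mJ/cm2 for 10 weeks and was then raised by 10 mJ/cm2 each week up to 300 mJ/cm2 at week 22, where it stayed until week 40. Each sample was hybridised to 1 single-colour Agilent array, and both arrays lay on the same slide and were read in the same scan. The comparison asks which genes differ in the UVB-induced tumour when P2ry6 is deleted. On the wild-type-labelled array 57.8% of non-control spots were well above background, with a median signal of 39.9 and a 75th percentile of 498. On the knockout-labelled array the same values were 57.9%, 40.0 and 456. With 1 array per genotype there was no biological replicate, so no test was run, no p-value is given, and genes and gene groups are described by size alone. The error that could be measured was technical. The difference between the arrays had an SD of 0.14 log2 units for a single spot, from 292 probes with replicate spots, and an SD of 0.38 between different probes of one gene.

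P2ry6 itself was not lower on the array labelled as its knockout. Its level relative to the array's 75th percentile was −0.63 (log2) on the wild-type-labelled array and 0.66 on the knockout-labelled array, a difference of 1.29 ± 0.01 (SD, n = 2 probes), or 2.44-fold higher. Both probes were well above background on both arrays. The probe at chromosome 7, 108086152 to 108086211 (mm9, minus strand), read 364 signal units on the wild-type-labelled array and 835 on the knockout-labelled array, and the probe at 108112251 to 108112310 read 137 and 318. Which part of the gene was deleted is not given in the sources used here, and a probe outside the deleted part does not check the label. Because this gene goes against the label, the arrays are named by their labels throughout, and each direction rests on those labels. Markers of macrophages, which express P2Y receptors, were also higher on the knockout-labelled array, with a median difference of 0.62.

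The genes that were lowest on the knockout-labelled array included several lipid enzymes. Fa2h, which hydroxylates fatty acids, was 134-fold lower (log2 difference −7.06), Awat1, which makes wax esters, was 109-fold lower (−6.77), and Elovl3, an elongase of very long chain fatty acids, was 101-fold lower (−6.65). Fcgbp, a secreted mucin-like protein that binds IgG, was 151-fold lower (−7.23). Far2, a fatty acyl-CoA reductase, was 35.7-fold lower, and Elovl6, another elongase, was 24.1-fold lower. The lipase family member Pnpla5 differed by −6.14 ± 0.20 (SD, n = 2 probes). AAdacl4fm3 (−6.44), Dgat2l6 (−6.39), a relative of the triglyceride-forming enzyme Dgat2, the proliferin family member Prl2c5 (−5.65), the phosphatidylcholine transfer protein Pctp (−5.48) and the glycerol phosphate dehydrogenase Gpd1 (−4.61) were lower too. Chil3, a chitinase-like protein of alternatively activated macrophages, was 29.9-fold lower, Il13ra2, a decoy receptor for IL-13, was 25.2-fold lower, and Tslp, an epithelial cytokine, was 18.8-fold lower. The probes of Fa2h (chromosome 8, 113869119 to 113869178), Awat1 (chromosome X, 97773128 to 97773187) and Elovl3 (chromosome 19, 46209325 to 46209384) are placed on mm9 by the array files.

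Differences in the other direction were smaller. Acta1, the actin of skeletal muscle, was 14.3-fold higher on the knockout-labelled array (log2 difference 3.84), from a probe at chromosome 8, 126416197 to 126416256 (mm9). Gprin3 was 12.8-fold higher, the zinc finger gene Repin1 10.3-fold, the olfactory receptor gene Olfr1153 9.72-fold and the retinol-binding protein gene Rbp4 8.90-fold. Cx3cr1, the fractalkine receptor of monocytes and macrophages, was 6.88-fold higher, and S100b, a calcium-binding protein of Schwann cells and other glia, was 6.06-fold higher. The actin-bundling protein gene Espn differed by 2.88 ± 0.32 (SD, n = 2 probes) and Golga7b by 2.84 ± 0.48 (SD, n = 2 probes). Mrgpra2a (2.94), Ccnjl (2.89), the neuropeptide gene Cort (2.66), Xpnpep2 (2.60) and Eid2 (2.60) were also among the 15 genes with an established symbol that had the greatest positive differences. Several were dim on the wild-type-labelled array, whose lowest signal well above background was −4.29 (log2 relative to the 75th percentile). There Gprin3 read −4.02, Acta1 −3.88, Rbp4 −3.87, Espn −3.81, Ccnjl −3.78, Mrgpra2a −3.76, Cort −3.52, Olfr1153 −3.27 and Golga7b −3.26. Their folds rest on weak signals and are imprecise. Repin1, Cx3cr1, S100b, Xpnpep2 and Eid2 were brighter there, from −1.78 to −0.79.

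Of 19873 genes measured on both arrays, 957 (4.82%) were at least 2-fold higher and 1002 (5.04%) at least 2-fold lower on the knockout-labelled array. The tails were unequal: 92 genes were at least 4-fold higher and 164 at least 4-fold lower, and 1 gene against 18 passed 16-fold. The median difference over all measured genes was −0.06 with an SD of 0.65, and the 29993 probes measured on both arrays correlated at r = 0.973 (Pearson) and 0.965 (Spearman) across probes, which are not independent replicates. The counts depended on the scale: relative to 8 spike-in control probes every difference would read 0.47 lower, which leaves 315 genes at least 2-fold higher and 3198 at least 2-fold lower, while normexp background correction left 368 and 578.

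**Figure D1:**
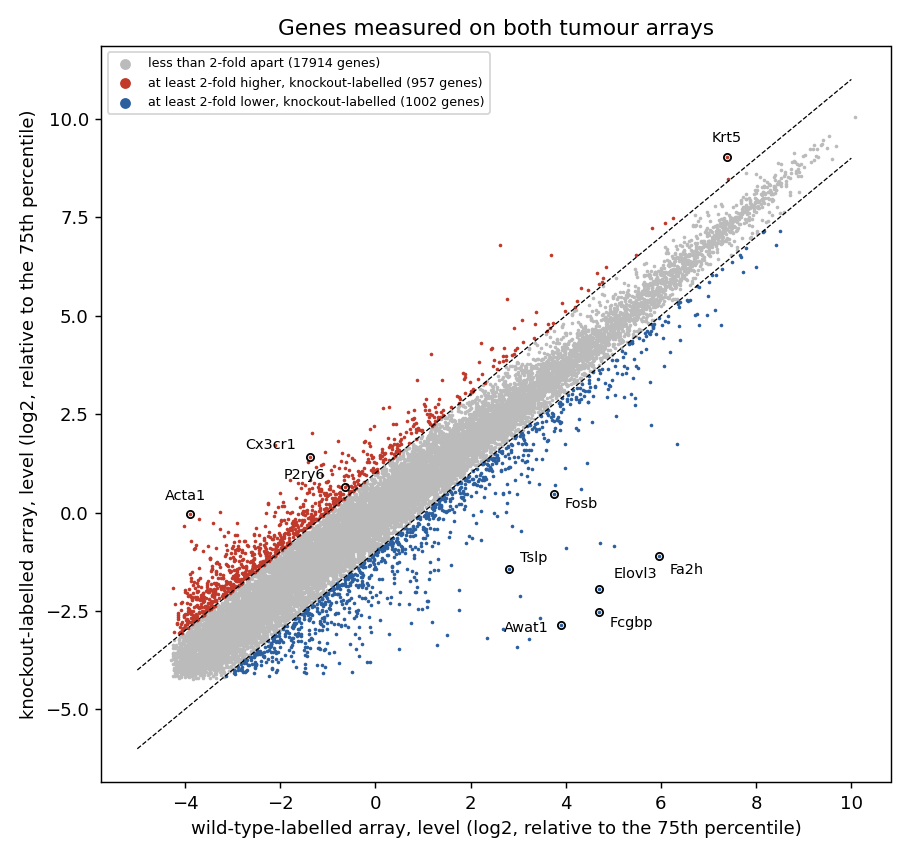
Levels of 19873 genes on the wild-type-labelled (x axis) and knockout-labelled (y axis) array, both in log2 relative to the array's 75th percentile, with dashed lines at a 2-fold difference. Of these, 957 genes (red) lie at least 2-fold above equality and 1002 (blue) at least 2-fold below, and Fcgbp, Fa2h, Awat1 and Elovl3 lie farthest below among the circled genes.

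Some genes were well above background on one array only and have a bound in place of a fold. Of 1012 genes above background on the knockout-labelled array alone, 229 had a bound of at least 2-fold, led by Cd276, an immune checkpoint ligand of the B7 family, at least 26.0-fold higher. Zfp979, a zinc finger gene, was at least 23.2-fold higher, the histone H2A variants H2al1e and H2al1m at least 12.9-fold and 7.26-fold, and the potassium channel Kcnj10 at least 7.53-fold. Of 1089 genes above background on the wild-type-labelled array alone, 266 had such a bound, led by Chil4, a chitinase-like relative of Chil3, at least 283-fold lower on the knockout-labelled array. The carboxylesterase Ces4a was at least 112-fold lower, the cytochrome P450 Cyp2g1 at least 52.7-fold, Aadacl4fm2 at least 47.4-fold and the slow-muscle myosin-binding protein Mybpc1 at least 41.3-fold. Under normexp correction 24 and 70 genes had a bound of at least 2-fold.

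Within the epidermis, markers of the sebaceous gland and of differentiated layers were lower on the knockout-labelled array, while the basal layer as a group lay near 0. Of 18 sebaceous gland markers, 13 were at least 2-fold lower, 0 higher and 5 neither, with a median difference of −1.62, below all 10000 random lists of matched expression. Fa2h, Awat1, Elovl3 and Far2 led them. Of 23 suprabasal and cornified layer markers, 13 were at least 2-fold lower, 0 higher and 10 neither (median −1.08, below all random lists). The transglutaminase Tgm3, which cross-links the cornified envelope, differed by −2.17 ± 2.18 (SD, n = 2 probes, at −3.71 and −0.64), the cornification protease Casp14 by −1.85, the desmosomal cadherin Dsg1a by −1.66 and the early differentiation keratin Krt1 by −1.62. Of 23 markers of hyperproliferative and stressed epidermis, 10 were at least 2-fold lower, 1 higher and 12 neither (median −0.92, below all random lists). Among these were the serpin Serpinb3a (−2.50), the envelope precursor Sprr3 (−2.14), the psoriasin homologue S100a7a (−2.05) and the interleukin-36 gene Il1f6 (−1.62). The member that was higher, the iron-siderophore binding protein Lcn2 (2.14-fold higher), was singled out after its value was seen.

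Basal keratinocyte markers had a median of −0.02 on the main scale, which became 0.10, 0.17 and 0.06 under quantile normalization, loess normalization and the authors' deposited values, and 0.03 with no filter on dim probes. Of 18 members, 1 was at least 2-fold higher, 0 lower and 17 neither. That member was Krt5, a keratin of basal cells, at 1.66 (3.16-fold higher), whereas its partner keratin Krt14, looked up after the value of Krt5 was seen, differed by 0.01. Simple epithelial and tumour progression keratins had 1 member at least 2-fold higher, 1 lower and 7 neither of 9, namely Krt8 (1.12) and the homeobox gene Pitx1 (−1.63). Their median of 0.09 turned to −0.35 without a filter on dim probes. Hair follicle and hair shaft markers were lower: of 14 measured members 5 were at least 2-fold lower, 0 higher and 9 neither (median −0.73, below all random lists), and 7 more were above background on the wild-type-labelled array alone. The inner root sheath keratin Krt71 differed by −1.89, the hair-shaft regulator Foxn1 by −1.25 and the hair keratins Krt86 and Krt31 by −1.12 and −1.11.

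**Figure D2:**
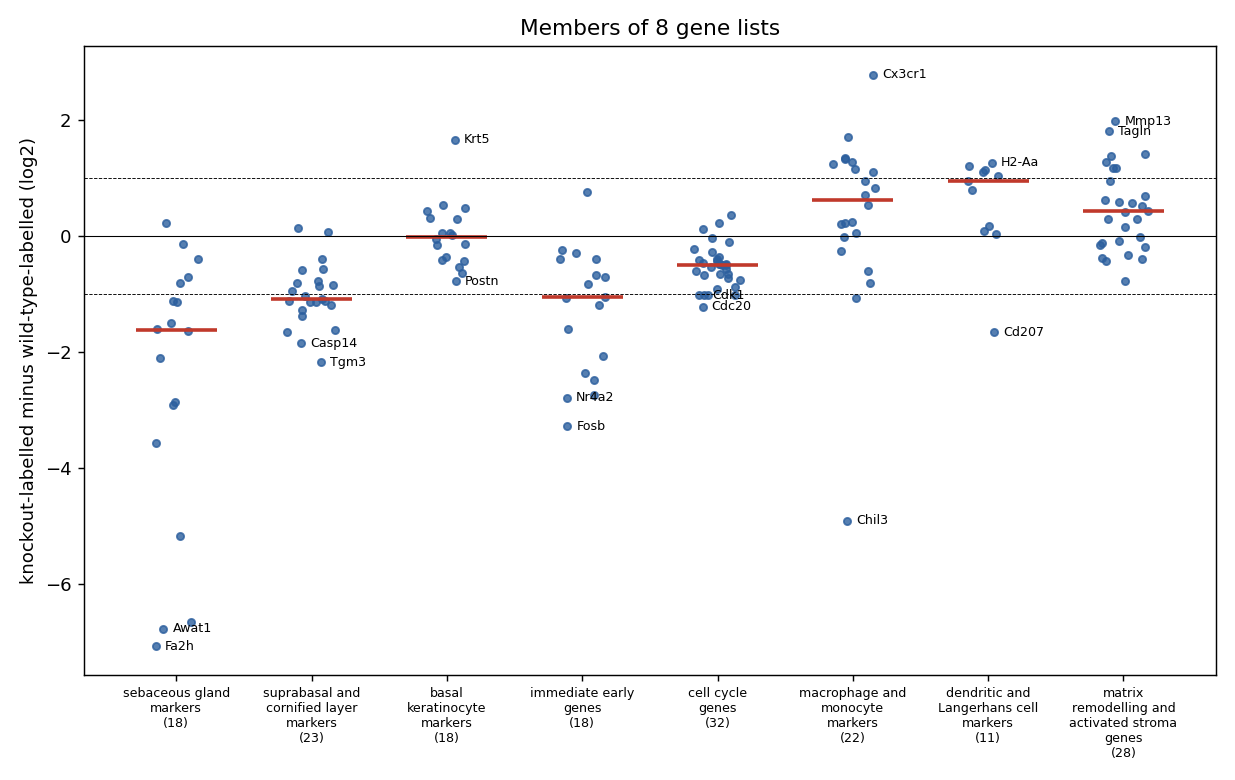
Difference between the knockout-labelled and wild-type-labelled array (log2, y axis) for each measured member of 8 gene lists (x axis, number of members in brackets), with the list median as a red bar and dashed lines at 2-fold. Sebaceous gland markers reach −7.06 at Fa2h with a median of −1.62, and basal keratinocyte markers have a median of −0.02 that is above 0 under quantile and loess scaling.

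Genes that respond within minutes to growth and stress signals were lower on the knockout-labelled array. Of 18 immediate early genes, 10 were at least 2-fold lower, 0 higher and 8 neither, with a median of −1.06, below all random lists. The AP-1 subunit gene Fosb was 9.71-fold lower, the orphan nuclear receptor genes Nr4a2 and Nr4a1 were 6.88-fold and 6.67-fold lower, and the stress transcription factor Atf3 was 5.61-fold lower. Of 20 output genes of the MAPK pathway, 7 were at least 2-fold lower, 0 higher and 13 neither (median −0.62, percentile 0.02 of random lists). These were led by the AP-1 subunit gene Fosl1 (−2.06), the EGF receptor ligand gene Areg (−1.79), Phlda1 (−1.62) and the ephrin receptor gene Epha2 (−1.37). Cell cycle genes were lower by less. Of 32 members 5 were at least 2-fold lower, 0 higher and 27 neither, yet 29 lay below 0 (median −0.50, percentile 0.02). The mitotic activator Cdc20 differed by −1.22, the mitotic kinase gene Cdk1 by −1.02, the spindle factor Tpx2 by −1.02 and the ubiquitin-conjugating enzyme Ube2c by −1.01.

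Medians of the Hippo and Wnt lists were small beside these. Of 20 YAP/TAZ target genes 0 were at least 2-fold apart in either direction (median 0.11, percentile 94.5, and 0.25, percentile 98.0, under loess normalization). They went both ways, 11 above 0 and 9 below, with Myof and Nuak2 at −0.97 each and Tgfb2 at 0.89. Of 18 Hippo pathway components 2 were at least 2-fold higher, 0 lower and 16 neither, with the cofactor gene Vgll4 at 1.17 and the transcription factor gene Tead2 at 1.12. The Hippo list median of −0.14 came to 0.00 under quantile normalization and under the authors' values. Among 19 Wnt/beta-catenin target genes 3 were at least 2-fold higher, 1 lower and 15 neither (median 0.26, percentile 98.5, and percentile 96.4 under loess normalization). The stem cell receptor genes Lgr6 and Lgr5 differed by 2.34 and 1.01, the transcription factor gene Lef1 by 1.13 and Tnfrsf19 by −1.53. Of 22 Wnt ligands and receptors 2 were at least 2-fold higher, 3 lower and 17 neither (median 0.18, percentile 97.1): the ligand genes Wnt3 (−2.26) and Wnt3a (−1.94) were lower, and Wnt6 (1.84) and Wnt5b (1.06) higher. Among 20 purinergic receptors and nucleotide enzymes 2 were at least 2-fold higher, 2 lower and 16 neither. The UTP receptor gene P2ry2 was 2.97-fold lower, the adenosine receptor gene Adora2b 2.39-fold lower and the ectoenzyme gene Enpp1 2.12-fold higher, beside P2ry6 itself. The median of this list, −0.08 (percentile 28.0), became 0.19 under the stricter filter on dim probes, 0.05 with no filter and 0.04 with the brightest probe per gene.

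Among immune cells, macrophage and dendritic cell markers were higher on the knockout-labelled array. Of 22 macrophage and monocyte markers 8 were at least 2-fold higher, 2 lower and 12 neither (median 0.62, above all 10000 random lists, and 0.28 without a filter on dim probes). Cx3cr1 was 6.88-fold higher, the Fc receptor gene Fcgr1 3.27-fold and the efferocytosis receptor gene Mertk 2.55-fold, against Chil3 at 29.9-fold lower. Of 11 dendritic and Langerhans cell markers 5 were at least 2-fold higher, 1 lower and 5 neither (median 0.95, above all random lists). The MHC class II gene H2-Aa was 2.40-fold higher, the integrin gene Itgax 2.31-fold and the MHC class II activator gene Ciita 2.21-fold, while Cd207, the langerin of Langerhans cells, was 3.15-fold lower. Neutrophil markers were mixed (3 at least 2-fold higher, 1 lower and 11 neither of 15, median 0.16, percentile 93.1), with the lectin gene Clec4d 2.99-fold higher, Retnlg 2.83-fold, the formyl peptide receptor gene Fpr2 2.60-fold and Stfa2l1 2.47-fold lower.

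Lymphoid and mast cell markers were lower or mixed. Among 17 T and NK cell markers 0 were at least 2-fold higher, 3 lower and 14 neither, namely the granzyme genes Gzmb (6.15-fold lower) and Gzma (2.83-fold) and the adhesion gene Cd2 (2.44-fold). The list median of −0.21 (percentile 5.33) became 0.22 under the stricter filter. Of 8 B and plasma cell markers 1 was at least 2-fold higher, 2 lower and 5 neither (median −0.53, percentile 0.95, and −0.28 with no filter on dim probes and −0.31 under normexp correction), with the immunoglobulin joining chain gene Jchain at 1.89 and the coactivator gene Pou2af1 at −1.72. Of 8 mast cell markers 1 was at least 2-fold higher, 4 lower and 3 neither. The mast cell protease genes Mcpt4, Cma1 and Cpa3 were 5.78-fold, 5.55-fold and 4.67-fold lower and the IgE receptor gene Fcer1a 2.10-fold lower, and the list median of −0.87 (percentile 0.02) turned to 0.19 under the stricter filter. That filter drops members dim on either array, here and in the T and NK list, so it can remove those that fell furthest. Of 29 cytokines and chemokines 3 were at least 2-fold higher, 7 lower and 19 neither. Their median of −0.27 (percentile 2.60) became −0.014 with no filter on dim probes and −0.14 (percentile 13.4) under loess normalization. Tslp was joined by the alarmin gene Il33 (−2.64), the chemokine gene Ccl8 (−2.27) and Il6 (−2.21). Of 26 interferon response genes 4 were at least 2-fold higher, 0 lower and 22 neither (median 0.25, percentile 98.8): the ubiquitin-like modifier gene Isg15 (1.53), Ifit3 (1.33) and the antiviral GTPase genes Mx1 (1.33) and Mx2 (1.12).

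Stromal groups were higher on the knockout-labelled array on the main scale. Of 28 matrix remodelling and activated stroma genes 7 were at least 2-fold higher, 0 lower and 21 neither (median 0.43, above all random lists). The collagenase gene Mmp13 differed by 1.98, the actin-binding gene Tagln by 1.81, the osteopontin gene Spp1 by 1.42 and smooth muscle actin, Acta2, by 1.38 ± 0.90 (SD, n = 3 probes). Of 9 smooth muscle and pericyte markers 4 were at least 2-fold higher, 0 lower and 5 neither (median 0.52, percentile 99.6), with the proteoglycan gene Cspg4 at 1.07 and the calponin gene Cnn1 at 1.05 beside Tagln and Acta2. Of 15 endothelial markers 1 was at least 2-fold higher, the junction protein gene Esam (1.42), 0 lower and 14 neither (median 0.52, percentile 99.9, and 0.27 without a filter on dim probes). Of 21 fibroblast markers 1 was at least 2-fold higher, 1 lower and 19 neither, namely Dpt (1.32), which encodes dermatopontin, and Dpp4 (−1.37). The fibroblast median of 0.17 (percentile 97.8) became −0.02 under the stricter filter and −0.08 with the brightest probe per gene. Of 15 epithelial-mesenchymal transition genes 0 were at least 2-fold higher, 1 lower and 14 neither. This list pools mesenchymal genes such as Vim, Zeb1 and Zeb2 with the epithelial genes Cdh1, Grhl2, Ovol1, Esrp1 and Esrp2. A transition would move the 2 kinds in opposite directions, so the list median does not measure one. The transcription factor gene Ovol1, an epithelial identity factor, differed by −1.10 and the transition factor gene Zeb1 by 0.97, and the median of 0.43 (percentile 99.7) turned to −0.22 under the stricter filter. On the spike-in scale, 12 of the 16 lists with a median above 0 would lie below 0. The 4 that would not are the macrophage, dendritic, endothelial and smooth muscle lists.

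Other cell types of skin were lower or mixed. Pigment cell markers were lower: of 5 measured melanocyte markers 3 were at least 2-fold lower, 0 higher and 2 neither (median −1.77, below all random lists), and 3 more were above background on the wild-type-labelled array alone. The melanosome gene Pmel was 8.40-fold lower, the melanin synthesis gene Dct differed by −2.82 ± 2.72 (SD, n = 2 probes) and Mlana by −1.77. Of 9 adipocyte markers 3 were at least 2-fold lower, 0 higher and 6 neither (median −0.76, percentile 0.11, and −0.27 without a filter on dim probes), with the lipid droplet genes Plin4 and Cidec 15.8-fold and 10.1-fold lower and the fatty acid carrier gene Fabp4 3.19-fold lower. Adipoq, Plin1, Retn, Cfd, Ucp1 and Car3 of the same list were above background on neither array. Of 9 Schwann and neural markers 2 were at least 2-fold higher, 1 lower and 6 neither: S100b (2.60) and the adhesion gene Ncam1 (1.19) against the myelin gene Mbp (−2.21). Their median of 0.03 (percentile 53.2) became −0.06 under quantile normalization and the authors' values and −0.09 under loess. Of 12 skeletal muscle markers only Acta1 was at least 2-fold apart (1 higher, 0 lower, 11 neither), and the median of −0.10 (percentile 23.6) became 0.02 under normexp correction and 0.24 with no filter on dim probes. Of 8 red blood cell markers 0 were at least 2-fold apart (median −0.24, percentile 25.8).

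Among stress and housekeeping groups the unfolded protein response stood apart. Of 18 members 3 were at least 2-fold lower, 0 higher and 15 neither, and 17 lay below 0 (median −0.67, below all random lists), with the glutathione-degrading enzyme gene Chac1 at −1.69, the pseudokinase gene Trib3 at −1.21 and the endoplasmic reticulum stress gene Herpud1 at −1.07. Of 21 p53 target genes 1 was at least 2-fold higher, 1 lower and 19 neither (median 0.11, percentile 97.4, but −0.11 under the stricter filter and −0.02 with the brightest probe per gene). The kinase gene Plk3 differed by −1.01. Trp53inp1 read 1.81 from 1 probe but −0.40 when spots marked as outliers by the scanner software were kept, and the list median then became −0.01. Of 20 nucleotide excision repair genes, which remove UV lesions from DNA, 0 were at least 2-fold apart (median −0.15, percentile 23.5). Of 25 hypoxia and glycolysis genes 0 were at least 2-fold apart, and the median of −0.02 (percentile 95.1) became 0.12 under quantile normalization and the authors' values and 0.11 under loess. Of 19 NRF2 target genes 1 was at least 2-fold higher, 3 lower and 15 neither (median −0.30, percentile 21.7): the glutathione peroxidase gene Gpx2 (1.40), and Gsta4 (−1.27), Me1 (−1.26) and Aldh3a1 (−1.17). Of 28 ribosomal protein genes and 16 reference genes, Rpl13a, which is in both lists, was at least 2-fold higher (1.41), 0 were lower and 27 and 15 were neither. The ribosomal median of −0.11 (percentile 86.8) became 0.04 and 0.14, and the reference gene median of −0.04 (percentile 90.5) became 0.06 and 0.08, under quantile and loess normalization, and both were above 0 under the authors' values too.

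As a check of the sex label, Xist, the transcript of the inactive X chromosome in females, was above background on neither array. The Y-linked genes Eif2s3y (−0.38), Uty (0.33) and Kdm5d (0.19) were measured on both arrays and 0 of these 3 were 2-fold apart (median 0.19, percentile 69.6). Ddx3y was above background on the wild-type-labelled array alone, from 1 probe that read 157 signal units there and 15.4 on the knockout-labelled array. Across the 40 lists, 9 medians lay above and 12 below the central 95% range of their random lists, against 2 of 40 for lists of genes drawn at random. The percentile describes these arrays and is not a test of genotype. Members above background on a single array do not enter a median. Among immune cell and stromal lists, Fpr1, Cd8a, Ms4a1, Tpsab1 and Des were above background on the knockout-labelled array alone. On the wild-type-labelled array alone were Cd163, Ctla4, Pax5, Ms4a2, Mfap5 and Twist1. Cd163 and Mfap5 thus go against the macrophage and fibroblast medians, and the T and NK, B and plasma and mast cell lists have such members on each array.

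**Figure D3:**
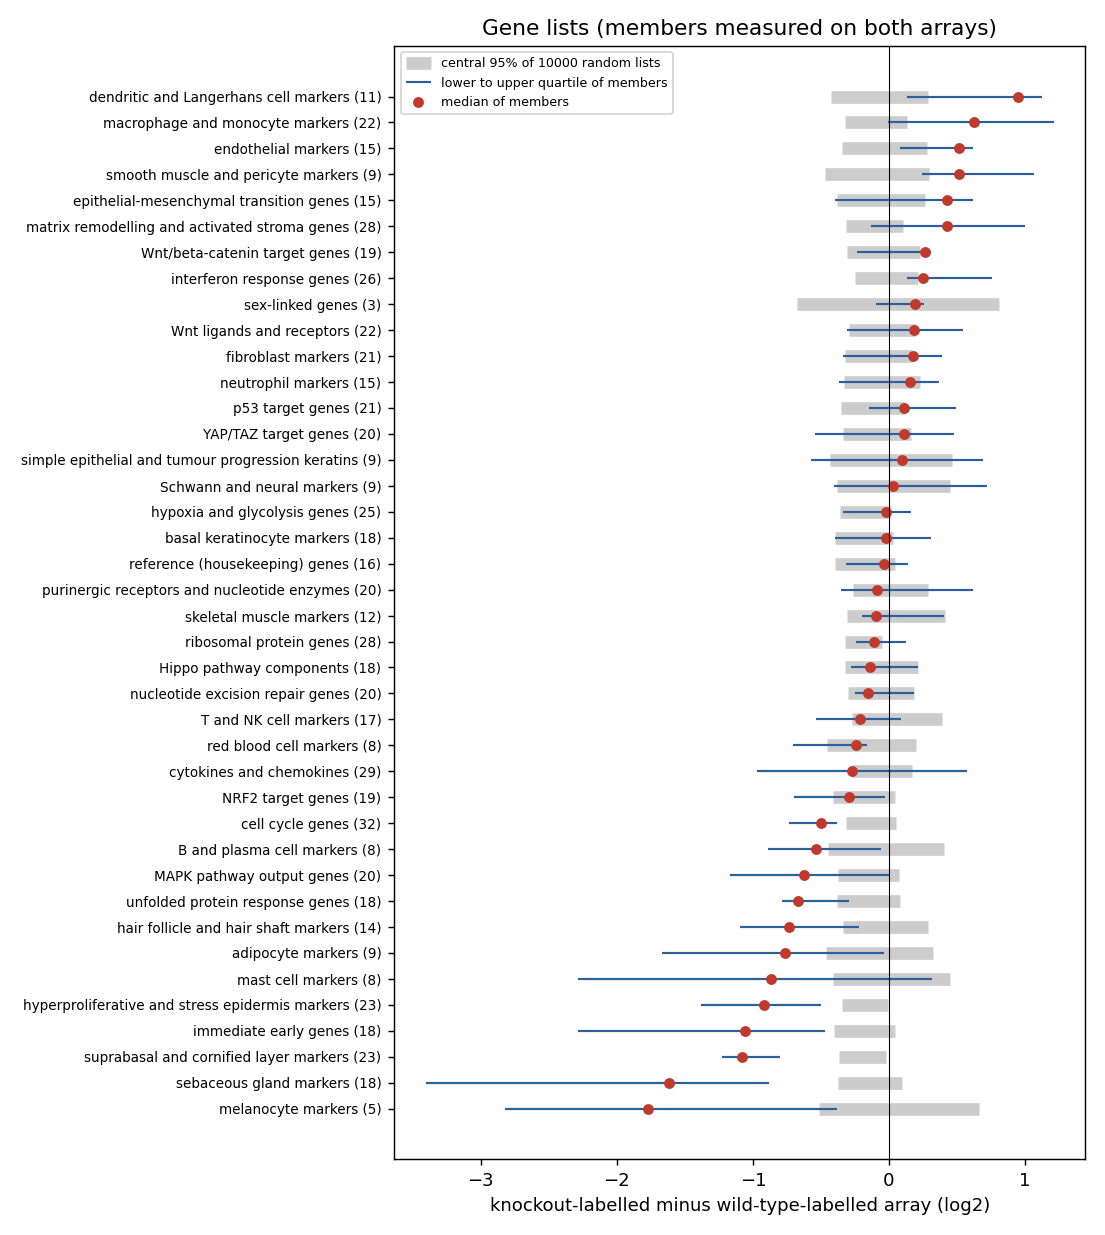
Median difference between the knockout-labelled and wild-type-labelled array (log2, x axis) of 40 gene lists (y axis, number of measured members in brackets), with the members' lower to upper quartile as a blue line and the central 95% range of 10000 random lists of matched expression as a grey bar. The dendritic cell list has the highest median (0.95) and the melanocyte list the lowest (−1.77), and 14 of the 40 medians take the other sign under at least 1 other setting.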

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

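Values are differences in log2 units, knockout-labelled minus wild-type-labelled, and the spike-in scale was chosen after seeing the data. No paired analysis was possible because each group has 1 array, and for the same reason no replicate could be left out. Of the 40 list medians, 26 kept their sign under every alternative that gave them a value, the spike-in scale apart, and 14 did not. Of the values given for each alternative, 319 counts, list medians and P2ry6 differences stayed within a factor of 1.5 (counts) or the technical spread of 0.14 (differences) and 81 did not. For single named genes 1173 values stayed within the spread and 308 moved further, among them Trpm1, less than 2-fold apart at 0.51, which came to −0.65 with no filter on dim probes. Of the named genes at least 2-fold apart 1 changed sign: Trp53inp1, which read 1.81, came to −0.40 when spots marked as outliers were kept, which brings back a brighter probe that was marked non-uniform on the wild-type-labelled array. Over all genes at least 2-fold apart, named or not, 4 changed sign with no filter on dim probes, 2 with the stricter filter, 3 with the brightest probe per gene, 1 with outlier spots kept and 0 in the other settings. Keeping those spots, and centring on the median of probes above background, moved none of the counts, list medians or the P2ry6 difference beyond these limits. A bound for genes seen on one array only was not computed without a filter, with the stricter filter, with the brightest probe per gene or at the 3-fold threshold, and the 3-fold threshold gives no list median. Signal over background limits the rest: 15325 genes gave no level on either array.

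The counts of genes at least 2-fold higher and lower, 957 and 1002, became 368 and 578 under normexp correction, 2244 and 2135 with no filter on dim probes, 256 and 492 with the stricter filter, which tests fewer genes, 241 and 311 at a 3-fold threshold, and 315 and 3198 on the spike-in scale. Genes on one array only with a bound of 2-fold became 24 (knockout-labelled) and 70 (wild-type-labelled) under normexp correction. That setting adds an offset of 50 to each signal, where the median signal was 39.9 (wild-type-labelled) and 40.0 (knockout-labelled). An added constant makes folds between dim signals smaller by arithmetic, so fewer bounds and fewer 2-fold calls among dim genes follow from the setting. How much of the drop the offset accounts for was not tested. The P2ry6 difference was 1.105 under normexp correction and 0.82 on the spike-in scale.

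For the list medians that follow, the cause of each move was not tested. Under normexp correction the medians were −0.46 for hair follicle, 0.20 for epithelial-mesenchymal transition, 0.35 for endothelial, −0.059 for T and NK cell, −0.31 for B and plasma cell, 0.71 for dendritic cell, −0.34 for mast cell and −1.37 for melanocyte genes. Quantile normalization gave 0.27 for YAP/TAZ targets, 0.0042 for Hippo components, −0.85 for suprabasal, −0.76 for hyperproliferative, 0.23 for simple epithelial, 0.78 for macrophage, −0.12 for cytokine, 0.12 for hypoxia, −0.47 for unfolded protein response, −0.13 for NRF2 target and 0.038 for ribosomal protein genes. The authors' deposited values gave, in the same order, 0.28, 0.0036, −0.87, −0.78, 0.23, 0.80, −0.12, 0.12, −0.48, −0.14 and 0.034. Under loess normalization YAP/TAZ targets came to 0.25, basal keratinocyte genes to 0.17, suprabasal genes to −0.88, hyperproliferative genes to −0.67, red blood cell genes to −0.078, unfolded protein response genes to −0.47 and ribosomal protein genes to 0.14. With no filter on dim probes the medians were −0.35 for simple epithelial, −1.03 for hair follicle, 0.085 for epithelial-mesenchymal transition, 0.27 for endothelial, 0.28 for macrophage, −0.28 for B and plasma cell, 0.70 for dendritic cell, −0.24 for mast cell, 0.24 for skeletal muscle, −0.27 for adipocyte, −0.014 for cytokine and 0.038 for sex-linked genes. The stricter filter gave 0.19 for purinergic, −0.45 for hair follicle, −1.08 for sebaceous gland, −0.023 for fibroblast, −0.22 for epithelial-mesenchymal transition, 0.78 for smooth muscle, 0.22 for T and NK cell, −0.79 for B and plasma cell, 0.19 for mast cell, −0.49 for cytokine, −0.11 for p53 target and −0.25 for reference genes. With the brightest probe per gene the medians were −0.16 for basal keratinocyte, −0.080 for fibroblast, 0.16 for epithelial-mesenchymal transition, 0.34 for endothelial, −1.60 for melanocyte and −0.22 for reference genes.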

Other observations

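The tests of gene families were chosen after the data were seen, as were those of the P2ry6 signal against a label swap and macrophage content, all 3 tests of the sebaceous gland markers, the loess test of the immediate early genes, and the reading of their handling test beside the whole MAPK list. Gene families that share a symbol stem were compared in the same way as the lists, 243 families with at least 8 measured members each, and 11 of them lay below the 0.1 or above the 99.9 percentile of matched random lists. Zinc finger genes of the Zfp stem were higher as a group on the knockout-labelled array: of 330 genes 34 were at least 2-fold higher and 6 lower, with a median of 0.30 that ranged from 0.18 to 0.30 over the settings but is smaller than the spike-in shift of 0.47. Zfp985 (2.51) and Zfp949 (2.40) led them. Of 9 Toll-like receptor genes the median was 0.84, led by Tlr12 (2.20) and Tlr1 (1.63), but it turned to −0.16 under the stricter filter on dim probes. The other 9 families were lower, and each median was below 0 in every setting run, though some came closer to it. The lowest medians among them were those of the Sprr, Tmprss and Lce stems. Of 10 type II transmembrane serine protease genes (Tmprss) the median was −1.25 (−1.27 to −0.75 over the settings), with Tmprss11g at −2.80 and Tmprss11f at −1.73, and kallikrein protease genes (Klk) had a median of −0.56 (−0.58 to −0.32), with Klk10 at −1.55. The small proline-rich genes (Sprr, median −1.57) and late cornified envelope genes (Lce, median −1.03) extend the suprabasal and stress lists, with which they share members.

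Phospholipase genes of the Pla stem had a median of −0.54 over 15 members, with the arachidonic acid-releasing enzyme gene Pla2g4a at −2.75 and the secreted phospholipase gene Pla2g2e at −2.55 against Pla2g7 at 1.42. Keratins as a whole (Krt, 36 genes) had a median of −0.51, with Krt78 at −1.90 and Krt5 at 1.66. ATPase subunit and transporter genes (Atp, 75 genes) were lower by less, with a median of −0.38 (−0.40 to −0.23 over the settings). Of these 75 only 1 was at least 2-fold lower and 0 were higher. The Ly stem (17 genes, −0.65) and the beta-protocadherins (Pcdhb, 12 genes, −0.61) were lower too, though with Ly6h at 1.99. Of 5966 transcripts without an established symbol 364 were at least 2-fold higher and 223 lower, against 593 and 779 of 13907 named genes. Both medians were slightly below 0 (−0.011 and −0.080), less than the spike-in shift, so it is the counts past 2-fold alone that differ in direction.

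P2ry6 read 2.44-fold higher on the array labelled as its knockout. Strain DNA that flanks a targeted gene could shift probe readings around it. Of 199 genes within 10 Mb, 17 (8.54%) were at least 2-fold apart, at the 35.5 percentile of 499 windows over the genome. That argues against readings shifted over the whole region. A share over many genes cannot speak to P2ry6 itself or its nearest genes. Close by, P2ry2, probed at chromosome 7, 108145553 to 108145612 (mm9), was 2.97-fold lower. Swapped array labels cannot be told apart from correct ones: the signal on the wild-type-labelled array (−0.63, log2 relative to the 75th percentile) was well above background at both probes, as it was on the other array, so neither array lacks the probed parts of the transcript, and the deleted part is not known here. A higher content of macrophages may contribute and also stays open: the macrophage list median of 0.62 lay above all random lists but below the 1.29 of P2ry6, and among its brightest members Apoe was 1.16-fold and Lyz2 2.15-fold higher. A rise of P2ry6 transcript in the knockout tumour was not tested.

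Sebaceous gland markers had a median difference of −1.62. A lower share of keratinocytes of all kinds, by as much as this median, is argued against by the basal keratinocyte list (median −0.022, quartiles −0.40 and 0.31). On the spike-in scale all of these values would read 0.47 lower, and a smaller loss of keratinocytes stays open. Loess normalization, which takes out a smooth trend with intensity shared by all probes, left the sebaceous median at −1.52. That argues against such a trend as the source, but the random lists were already matched on level, so the test adds little. Less gland tissue in the sampled piece of tumour may be the source and cannot be told apart from lower lipid synthesis in the gland. Of 8 list members picked as gland markers after the data were seen, 7 were at least 2-fold lower. These ranged from 2.17-fold for Mc5r to 134-fold for Fa2h, while Krt79 was 1.32-fold lower. Whether the 8 are restricted to the gland was not checked. Over the whole list 17 of 18 members lay below 0, and Pparg was at 0.22. Markers of hair follicles and melanocytes, which lie in the same part of the skin as the gland, were lower too. The adipocyte list median was also lower, but Adipoq, Plin1, Retn and Cfd were above background on neither array and Lep differed by 0.02. The adipocyte list therefore does not show by itself that less fat tissue was sampled. A difference of genotype in gland formation stays open and was not tested.

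Immediate early genes had a median difference of −1.06. Loess normalization, which takes out a smooth trend with intensity shared by all probes, left −0.93. That argues against such a trend as the source, but the random lists were already matched on level, so the test adds little. A difference in handling or time to freezing between the samples cannot be told apart from lower MAPK signalling. A set of 13 output genes of the pathway, feedback regulators among them and none from the immediate early list, had a median of −0.31. That lay inside the −0.43 to 0.14 of matched random lists. The 13 genes went both ways, from Fosl1 (−2.06) and Epha2 (−1.37) to Etv4 and Spred2 (0.67 each). They also leave out Areg, Phlda1, Ier3, Hbegf and Ereg, each at least 2-fold lower, and Dusp5 and Tgfa, which were not. The whole list of 20 MAPK output genes (median −0.62) lay below its random range of −0.38 to 0.07. It differs from the 13 genes only by these members, so it does not decide between handling and signalling. A genotype difference in signalling stays open and was not tested.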
